A study of Homo sapiens with 2 samples.

How the data were processed

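Total RNA from 2 stably transfected lines of SK-N-MC, a human cell line described by the submitters as a neuroepithelioma line, was measured on Affymetrix U133 Plus 2.0 expression arrays, per the labels' protocols and the series description. 1 array carried RNA from cells with the empty expression vector (vector control, clone 1) and 1 array carried RNA from cells with the human melanotransferrin cDNA in the same vector (hyperexpression clone 4). Groups were taken from the sample labels.

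The deposited values are linear intensity values (probe set signals) with 1 decimal, 1 per probe set and array. GCOS version 1.3 was used, per the submitters' processing notes; the summary algorithm, the scaling target and detection calls are not given in the sources used here. The intensity values as deposited had been scaled per array: after dropping the lowest and highest 2% of the 54675 probe sets, the mean signal was 1000.12 on both arrays. Such global scaling sets the total of each array to the same level, so a change that affects most transcripts alike cannot be seen in these values. The signals ran from 0.4 to 93926.7 on the control array and from 0.8 to 96587.4 on the clone array. No scanner-level data were used here.

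Probe sets were named with the platform annotation of 2016, in which 41097 had 1 gene symbol, 1801 had several and 11777 had none here; only the first kind was used for genes. Symbols were updated by gene ID through the RefSeq table of assembly GRCh38.p14, which matched 41043 of these probe sets and gave a chromosome for 19726 of 19775 genes. The table was used for names, chromosomes and the order of neighbouring genes, and no coordinates are given because no build is stated for the array data. Each gene was represented by its probe set with the highest mean signal. Some genes of the lists are not analysed here because no single-gene probe set was named for them.

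No detection calls were used. A floor was set at a signal of 208, the 90th percentile over both arrays of 191 probe sets for olfactory receptors, bitter taste receptors and hair keratin-associated proteins, genes this cell type should not express. A gene below the floor on both arrays was counted as not measured. A gene below it on 1 array was compared with the floor, so its ratio is a lower bound and is written as "at least"; a bound under 2 does not show that a gene lay within 2-fold. This left 12663 measured genes, 10795 above the floor on both arrays, 1426 on the control array only and 442 on the clone array only.

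With 1 array per group, no test between the groups was possible and no p-value is given. Genes were counted by a fixed size, a ratio of 2 or more in either direction. The only repeat measurement was the agreement of different probe sets for the same gene within the same pair of arrays. Over 5387 genes with 2 or more probe sets above the floor on both arrays, the log2 ratios of a gene's probe sets had a pooled SD of 0.35; it was 0.40 where the dimmest probe set had a mean signal under 500 and 0.21 where it was over 2000. This spread comes from probe sets read on the same RNA and arrays, so it covers disagreement between probe sets. It leaves out array-wide differences in RNA, labelling or hybridisation, and the variation between cultures and between clones. The log2 ratios of all these probe sets had an SD of 0.39, little above the pooled SD within genes. The number of arrays limits the precision of every value.

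There were 24 gene lists for pathways and 7 lists of cell type markers. A list's median log2 ratio is given relative to the median of all measured genes, which was -0.022, and was set against 10000 random lists of the same size matched on mean signal in 20 bins. The percentile among random lists describes these 2 arrays and is not a test of the transfection. A list needed 4 measured members for a median. Chromosomes were described in the same way over genes above the floor on both arrays.

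The gene lists and the rule for the genes named in the text were fixed before the data were examined. The rule took the transfected gene; the 12 genes per direction with the largest change among genes with 2 or more probe sets above the floor on both arrays, all changed the same way, ranked by the smallest change among them; genes below the floor on 1 array by every probe set with a bound of at least 4-fold, up to a fixed number; members of the lists at least 2-fold apart; and every analysed member of a list of genes that the submitters' group reported in melanotransferrin models. Members of a list not past 2-fold are named as examples of their list, picked after their values were seen.

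The scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data in which 200 genes had known changes and the probe set spread given above was added to the control signals of 19775 genes, with a signal-dependent trend that a loess removed. Of 50 genes changed 4-fold, 50 passed 2-fold in the true direction, as did 49 of 50 changed 3-fold and 4 of 50 changed 1.5-fold, against 33 of 12575 genes without a seeded fold; these counts are after the loess, whereas the reported values use the scaling as deposited. The seeded genes had a control signal of at least 4 times the floor. The same spread was drawn independently for each probe set at every signal. The counts thus do not cover changes in dim genes, nor give the share of the reported 2-fold genes that are real. Of 200 unchanged lists, 12 lay outside the central 95% of random lists. Genes regulated together were not simulated. Alternatives were another scaling of the arrays (median centring, quantile, loess with a span of 0.3, hybridisation spikes, poly-A spikes). They also covered the floor, the choice of probe set, an added offset, the fold threshold and the set of genes included. Median centring and both spike scalings shift all log2 ratios alike. They thus change a relative median only through the floor and through which probe set of a gene is brightest. A median over a gene's probe sets was taken over those above the floor on at least 1 array.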

Results

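The series compared gene expression in SK-N-MC cells made to overexpress human melanotransferrin with the same cells carrying the empty vector. Melanotransferrin is a membrane-bound homologue of the iron carrier transferrin, first known as a melanoma antigen, and the comparison asks which transcripts differ when it is made in excess. SK-N-MC was named a neuroepithelioma line and is now assigned to the Ewing tumour family. Each group held 1 array, so every value below is a single measurement of 1 cell clone, with no replicate SD and no test between the groups. On the control array 50.8% of the 54675 probe sets lay above the floor of 208, and on the clone array 47.3%. Log2 signals of the 2 arrays had a Pearson r of 0.977 across the 10795 genes above the floor on both; genes are not independent replicates.

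Melanotransferrin itself was higher in the clone on 1 of its 4 probe sets. That probe set is annotated to the same transcript as the insert. It read 18.4 in the vector control, below the floor, and 4449.4 in the clone, so the signal was at least 21.4-fold higher. The other 3 probe sets for MELTF (chromosome 3) did not show this. The first read 245.8 in the control and 209.3 in the clone, and the others were below the floor on both arrays, at 64.4 and 125.5 and at 19.2 and 10.8. Whether these 3 lie outside the inserted cDNA was not tested here, since probe sequences were not used.

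Of 12663 measured genes, 153 were at least 2-fold higher in the clone and 240 at least 2-fold lower. Genes below the floor on 1 array made up 33 of the higher and 115 of the lower genes; above the floor on both arrays the counts were 120 and 125. The split depended on the scaling: centred on the hybridisation spikes it was 893 higher and 49 lower, and centred on the poly-A spikes 19 higher and 1573 lower. These scalings moved the median of all genes by 0.49 and -0.56 on the log2 scale, so directions below hold relative to all genes on arrays scaled to the same mean. Of 43 genes at least 2-fold higher with a second probe set above the floor on both arrays, 34 were higher and 6 were at least 2-fold higher on that probe set too. Of 31 such lower genes, 24 were lower and 5 at least 2-fold lower on it.

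The control probe sets differed between the arrays. The 18 probe sets for transcripts spiked in at hybridisation were all lower on the clone array, with a median ratio of 0.706. The 24 probe sets for poly-A transcripts, which are usually added to the RNA at the start, were all higher on it, with a median ratio of 1.53. The signal near the 3' end over that near the 5' end was 1.21 on the control array and 1.44 on the clone array for ACTB (beta-actin), and 0.920 and 0.951 for GAPDH. Probe sets for olfactory receptor, taste receptor and hair keratin-associated genes had a median signal of 67.4 on the control array and 44.0 on the clone array.

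**Figure D1:**
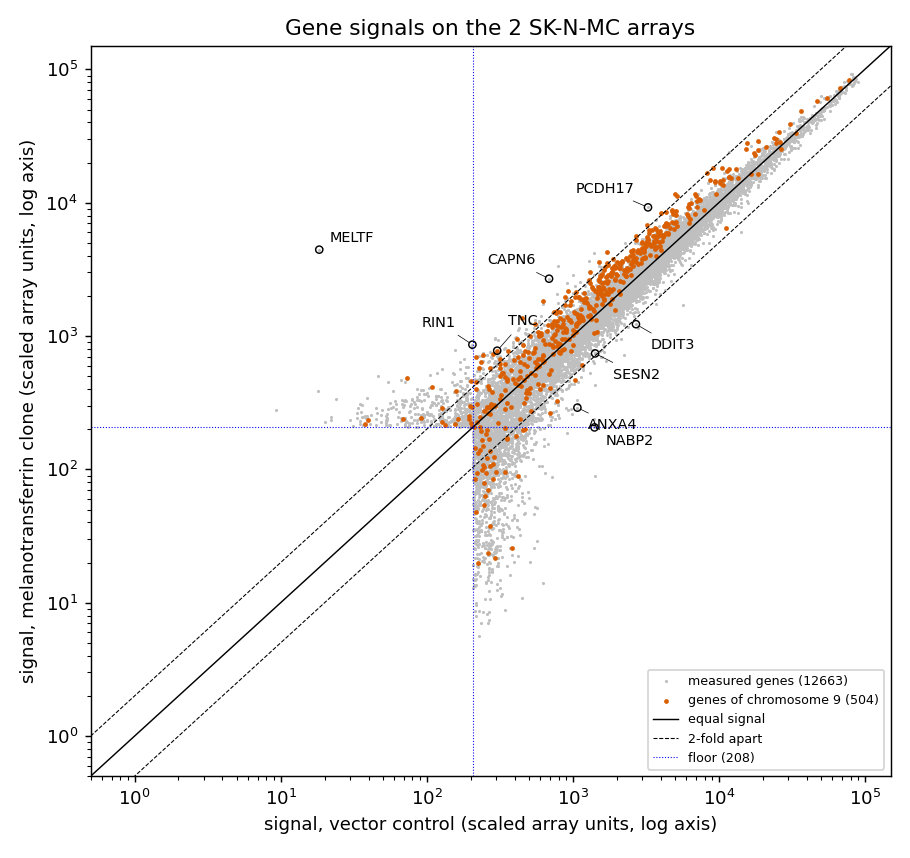
Signal of each measured gene on the vector control array (x axis) and the melanotransferrin clone array (y axis), both log axes in scaled array units, with genes of chromosome 9 in orange and the floor of 208 as dotted lines. MELTF stands at 18.4 against 4449.4, far from the other genes, and most chromosome 9 genes lie above the line of equal signal.

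Among genes with several measured probe sets that were all higher, CAPN6, a calpain family member without protease activity, was 3.91-fold higher, from 689.3 to 2694.8, and its second measured probe set gave a log2 ratio of 1.58. PCDH17, a protocadherin, was 2.82-fold higher, from 3279.4 to 9236, with log2 ratios of 1.49 to 1.77 over 3 probe sets. COL5A1, a chain of type V collagen, was 2.49-fold higher and its 3 probe sets ranged from 0.84 to 1.32 on the log2 scale. RABGAP1 was 2.31-fold higher, with a log2 ratio of 0.79 once probe sets with shared sequences were left out. SHISAL1 was 2.30-fold higher, OLFM3, an olfactomedin, 2.24-fold, PCSK5, a proprotein convertase, 2.14-fold, and TTF1, a termination factor of RNA polymerase I, 2.07-fold. CUTALP (1.88-fold), SLITRK6, a neuronal transmembrane protein (1.86-fold), CAMSAP1, a microtubule minus-end binding protein (1.73-fold), and PSIP1, a chromatin-bound coactivator (1.73-fold), completed the 12. Of these 12 genes, 7 lie on chromosome 9: COL5A1, RABGAP1, PCSK5, TTF1, CUTALP, CAMSAP1 and PSIP1. RIN1, a RAS effector with 1 probe set, was at least 4.15-fold higher, although its control signal of 205.8 was just under the floor.

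The lower group was led by ANXA4, a calcium-dependent phospholipid-binding annexin, which was 3.71-fold lower, from 1077.2 to 290.7, with log2 ratios of -1.89 and -1.65. COTL1, an actin-binding protein, was 2.60-fold lower, with a log2 ratio of -0.87 without probe sets of shared sequence. RARG, a retinoic acid receptor, was 2.27-fold lower, FAM118A 2.24-fold lower and CASP8, the initiator caspase of death receptors, 2.03-fold lower. SESN2, a stress-induced sestrin, was 1.92-fold lower. PPFIBP1 was 1.86-fold lower, a value that went to -0.049 on the log2 scale once probe sets with shared sequences were left out. PEX5, the peroxisomal import receptor, was 1.86-fold lower, GAP43, a growth cone protein, 1.84-fold, ZFYVE9, an adaptor of SMAD proteins, 1.83-fold, and RAB35, a small GTPase of endosomes, 1.74-fold. EPHA3, an ephrin receptor, was 1.83-fold lower on its brightest probe set and had a log2 ratio of -2.23 on the other measured probe set. None of these 12 lies on chromosome 9. NABP2, which binds single-stranded DNA, was at least 6.78-fold lower on its only probe set, with a clone signal of 206.6 just under the floor.

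No measured gene of iron metabolism passed 2-fold by the rule used here. The list held 35 genes, of which 32 had a single-gene probe set and 7 were below the floor on both arrays. FTH1, the ferritin heavy chain, and IREB2, another iron regulatory protein, were among the members without a value. Of 25 measured members of that list, 0 were counted as 2-fold higher and 0 as 2-fold lower, and their relative median of -0.11 lay at percentile 7.82 of random lists. On probe sets without shared sequences, 17 members were measured and the relative median was -0.23, at percentile 1.59 and so below the central 95%. The 5 members below the floor on 1 array have bounds only, which do not show that they lay within 2-fold. TFR2, the second transferrin receptor, read 390.5 and 173.5, STEAP3, a ferrireductase, 334.3 and 181.9, TMPRSS6, a regulator of hepcidin, 314.9 and 141.7, and CP, ceruloplasmin, 263.4 and 106.2, with log2 bounds of -0.91, -0.68, -0.60 and -0.34. HAMP, the iron hormone hepcidin, went the other way, at 189.5 and 346.1 with a bound of 0.73. Among all measured genes, 1426 were above the floor on the control array only and 442 on the clone array only. Background probe sets also read lower on the clone array, with medians of 67.4 and 44.0. A lower background can thus account for part of these bounds, which was not tested for these genes. TFRC, the transferrin receptor, read 27936 and 23232, and FTL, the ferritin light chain, read 64372 and 57290, log2 ratios of -0.27 and -0.17. SLC40A1, the iron exporter ferroportin, had a log2 ratio of 0.092. The largest higher value above the floor on both arrays was that of ACO1, the cytosolic aconitase that also acts as an iron regulatory protein, at 0.63; ACO1 lies on chromosome 9. The 21 measured genes of iron-sulfur cluster and haem synthesis had a relative median of 0.057 (percentile 53.96), also with 0 members past 2-fold; it turned to -0.14 (percentile 2.72, 13 members) on probe sets without shared sequences.

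The list of genes that the submitters' group reported in melanotransferrin models can rest in part on these arrays, so its values are not taken as independent evidence; 1 of its 4 members is not analysed here. All 4 probe sets for MEF2A, a myocyte enhancer transcription factor, were lower in the clone, with log2 ratios from -1.15 to -0.33. All 8 probe sets for TCF4, a basic helix-loop-helix transcription factor, were higher, from 0.025 to 0.93. APOD, a lipocalin, read 528.8 and 295.6 on its 1 probe set, 1.79-fold lower. None of the 3 passed 2-fold on its brightest probe set.

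Genes of the unfolded protein response and of amino acid stress were lower in the clone as a group. Of 30 members, 27 lay below the median of all genes, and the list's relative median of -0.41 was lower than every one of the 10000 random lists, whose central 95% ran from -0.080 to 0.14. DDIT3, a stress-induced transcription factor, was 2.21-fold lower and SDF2L1, an endoplasmic reticulum chaperone component, 2.06-fold lower. ATF3, another stress-induced factor, was 1.95-fold lower, PDIA4, a protein disulfide isomerase, 1.62-fold, the chaperone HSP90B1 1.60-fold, and ASNS, asparagine synthetase, 1.60-fold, from 15792 to 9898.9. HSPA5, a major chaperone of the endoplasmic reticulum, read 26885 and 25267, a log2 ratio of -0.090. VLDLR was the 1 member past 2-fold in the other direction, at 2.51-fold higher, from a control signal of 227.9 near the floor. Both HSPA5 and VLDLR lie on chromosome 9, and without that chromosome's genes the list's relative median was -0.45. Some members on other chromosomes also changed little: DNAJB9, DNAJC3, EDEM1 and PDIA6 had log2 ratios of 0.080, -0.071, -0.080 and -0.14.

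Genes of the hypoxia response stood higher, with 15 of 22 measured members above the median of all genes and a relative median of 0.29 (percentile 99.91). ANGPTL4 was at least 2.56-fold higher, and its control signal of 184.4 was under the floor. Neither of its 2 probe sets lay above the floor on both arrays. The median over its probe sets, 0.71 on the log2 scale, thus rests on bounds only. ADM, adrenomedullin, was 1.70-fold higher, PDK1, a pyruvate dehydrogenase kinase, 1.61-fold, and BNIP3, a mitophagy receptor, had a log2 ratio of 0.59. VEGFA stood at 0.073 on that scale. The 7 members below the median of all genes included LOX and P4HA2, with log2 ratios of -0.32 and -0.45. STC2, which is also a member of the stress list, was 1.66-fold lower. Of 17 glycolytic enzymes, HK1 was 2.49-fold and ALDOC 2.02-fold higher, each on 1 probe set and HK1 from a dim control signal of 220.8. The list's relative median was -0.072 (percentile 6.70), and 0.013 (percentile 42.56) as the median of each gene's probe sets. The 32 measured respiratory chain subunits had a relative median of -0.020 (percentile 16.98).

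Genes of the G1/S transition and DNA replication were slightly higher, with 27 of 37 above the median of all genes, a relative median of 0.20 and a percentile of 99.99; 0 passed 2-fold. TYMS, thymidylate synthase, had a log2 ratio of 0.59. FEN1, a flap endonuclease, was 1.46-fold higher and E2F1 1.44-fold, whereas CCND1, cyclin D1, had a log2 ratio of -0.26. For mitotic genes the relative median was 0.13 (percentile 97.68) over 35 genes, inside the central 95% of random lists in 3 of 14 settings, and MKI67 was 1.19-fold higher. Among 21 p53 targets, TP53INP1 was 2.21-fold higher, GADD45A 2.01-fold lower and PLK3 at least 2.13-fold lower, with a relative median of 0.017 (percentile 53.49) that turned direction in 4 of 14 settings, to -0.088 as the median of each gene's probe sets. Of 23 apoptosis regulators CASP8 alone passed 2-fold, and the relative median was -0.021 (percentile 22.69), turning to 0.034 on probe sets without shared sequences.

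Matrix and adhesion genes had relative medians just outside the central 95% of random lists. The 27 extracellular matrix genes had a relative median of 0.16 (percentile 97.51), with COL5A1 and TNC, tenascin C, as the members past 2-fold. TNC was 2.56-fold higher on its brightest probe set, the only 1 of its 3 above the floor on both arrays. The median of its measured probe sets, 0.67 on the log2 scale, rests in part on a bound. COL5A1 and TNC lie on chromosome 9. Without that chromosome's genes the matrix list had a relative median of 0.15 inside the central 95%. The 23 adhesion molecules and integrins had a relative median of 0.15 (percentile 99.02), led by PCDH17, and the 25 genes of TGF-beta and BMP signalling 0.16 (percentile 98.82). The TGF-beta value was -0.013 on probe sets without shared sequences, and this list too lay inside the central 95% without chromosome 9 genes. These 3 lists lay inside the central 95% in 8, 5 and 6 of 14 settings, in the order given. Genes of the plasminogen system, to which melanotransferrin has been linked, had a relative median of -0.12 (percentile 4.35) over 20 members with 0 past 2-fold, and -0.20 (percentile 0.38) as the median of each gene's probe sets; MMP14, a membrane-bound metalloprotease, was 1.89-fold lower and SERPINE2, a protease inhibitor, 1.66-fold higher.

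In the remaining pathway lists the relative median lay inside the central 95% of random lists as deposited. It was 0.090 for cholesterol synthesis, 0.098 for Ewing tumour genes, 0.070 for growth factor receptors and MAPK feedback, 0.053 for ribosomal proteins, 0.0087 for Wnt signalling, -0.080 for GPI anchor synthesis, -0.075 for oxidative stress and metallothioneins, -0.099 for neuronal differentiation and -0.19 for the interferon response. The interferon list was below the central 95% in 4 of 14 settings, at -0.32 with the floor at each array's median signal, and the Ewing list above it in 3. The neuronal list turned to 0.019 with the floor 2 times as high, and the Wnt, cholesterol and growth factor lists also turned direction in some settings. Single members past 2-fold in these lists were SFRP2, a Wnt inhibitor, at least 2.09-fold lower, the metallothionein MT1G, 2.15-fold higher, and the interferon-induced IFI44L, 2.18-fold higher. MT1G had a dim control signal of 232.4 on a probe set of shared sequence, the only 1 of its 2 above the floor on both arrays. The Ewing markers CD99 and NKX2-2 were bright on both arrays, with log2 ratios of 0.035 and 0.11. Of the 28 lists with a median, 7 lay outside the central 95%. About 1.4 would be expected by chance if members varied independently and lists shared none. The lists hold related genes and share some members, so that number may be too low. The 7 include the extracellular matrix list, whose median lay at its upper bound (0.15973 against 0.15972).

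**Figure D2:**
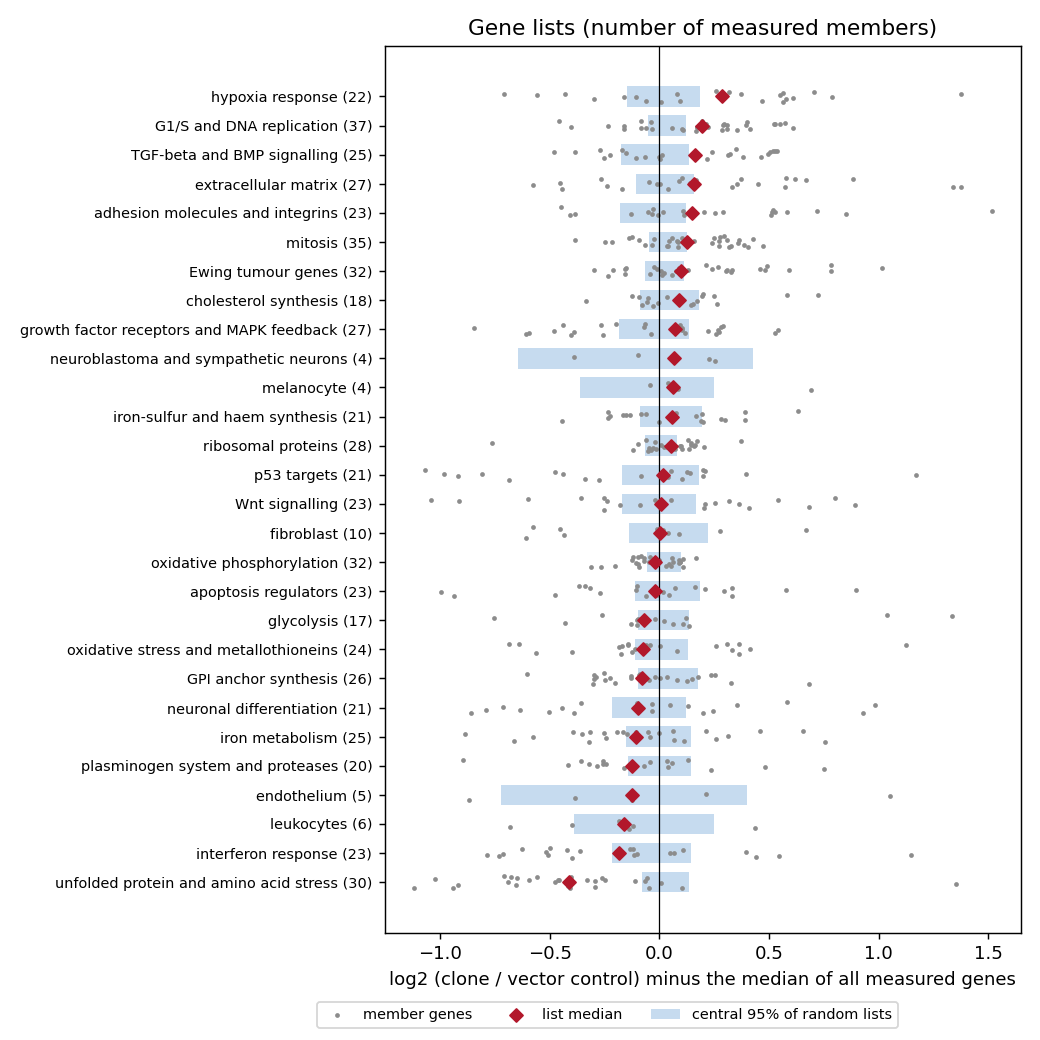
Log2 ratio of clone over vector control, relative to the median of all measured genes (x axis), for each gene list (rows, with the number of measured members). Grey points are member genes, red diamonds list medians and blue bars the central 95% of 10000 random lists; the stress list at -0.41 and the hypoxia list at 0.29 stand farthest from 0.

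Many markers of other cell types were below the floor, but most fibroblast markers were measured. Of 12 hepatocyte markers 11 were below it on both arrays, as were 8 of 11 epithelial, 7 of 12 endothelial and 7 of 11 melanocyte markers. So were 6 of 12 leukocyte, 6 of 10 sympathetic neuron and 2 of 12 fibroblast markers. Some were bright on both arrays. The fibroblast markers TWIST1 and COL3A1 read 20939 and 15266, and 12047 and 12188. PTPRC of the leukocyte list read 15581 and 13943, and KIT of the melanocyte list 6439.3 and 6726.3. The relative medians were 0.062 for melanocytes, 0.0035 for fibroblasts, -0.13 for endothelium, -0.16 for leukocytes and 0.064 for sympathetic neurons, all inside the central 95% of random lists in each setting run. Apart from the melanocyte list, which was higher in all 7 settings that gave it a median, each of these lists turned direction in some setting. The leukocyte value was -0.35 with the hybridisation spikes and 0.10 with the poly-A spikes. The endothelial value turned to 0.093 with quantile normalization and 0.063 with the poly-A spikes, the sympathetic value to -0.089 with the hybridisation spikes and the fibroblast value in 8 of 14 settings. Of 3 measured epithelial markers, all keratins of simple epithelia, the brightest, KRT18, read 9759.9 and 10363, a log2 ratio of 0.087. KRT7 was 2.27-fold lower and KRT8 2.08-fold lower, the latter with log2 ratios of -0.95 under quantile normalization and -0.99 under loess. CDH5, an endothelial cadherin, was at least 2.04-fold higher, its control signal of 169.2 being under the floor. The melanocyte list had 0 members past 2-fold.

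By chromosome, the genes of chromosome 9 stood apart. Their relative median was 0.47, a 1.38-fold higher signal in the clone, over 445 genes above the floor on both arrays, and 89.4% of them lay above the median of all genes; the central 95% of random gene sets ran from -0.031 to 0.033. Chromosome 9 held 30 of the 153 genes at least 2-fold higher, or 19.6%, but 3.98% of the measured genes, and 6 of the 240 lower genes. PAPPA, a protease of insulin-like growth factor binding proteins, was 1.99-fold higher. Chromosome 13 followed with a relative median of 0.13 over 209 genes, PCDH17 and SLITRK6 among them, and the other chromosomes ranged from -0.074 for chromosome 22 to 0.033 for chromosome 18. In all, 8 of 23 chromosomes lay outside the central 95% of random gene sets, and those other than 9 and 13 had relative medians below 0. Chromosome 9 genes are part of the reference, and leaving them out moved the median of all measured genes by -0.0096. Chromosomes 1, 14 and 19 passed their lower bounds by less than that. Their values were -0.028 against -0.020, -0.0382 against -0.0380 and -0.042 against -0.036. Without chromosome 9 genes, 123 genes were at least 2-fold higher and 234 lower.

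**Figure D3:**
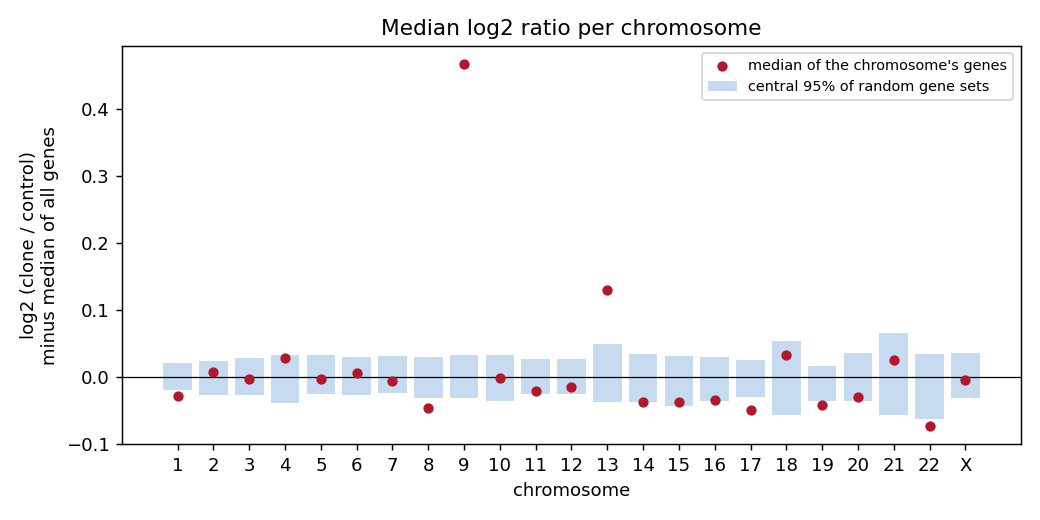
Median log2 ratio of clone over vector control for the genes of each chromosome, relative to the median of all genes above the floor on both arrays (y axis); blue bars are the central 95% of random gene sets of the same size and signal. Chromosome 9 stands at 0.47 and chromosome 13 at 0.13.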

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

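The added alternatives (poly-A spikes, chromosome 9 left out, only genes above the floor on both arrays, only bright genes) were chosen after seeing the data. No paired analysis was possible because each group held 1 array, and no array could be left out. The counts of genes higher and lower by 2-fold moved by over 1.5 times in these settings: 893 and 49 centred on the hybridisation spikes and 19 and 1573 centred on the poly-A spikes, which moved the median of all genes by 0.49 and -0.56; 71 and 47 with the floor 2 times as high; 42 and 38 with the floor added to both signals; 681 and 1067 at 1.5-fold and 16 and 29 at 3-fold; and 41 and 18 for genes with a mean signal over 1000. Only the lower count moved, to 125, for genes above the floor on both arrays. Under median centring, quantile normalization, loess, the floor at each array's median, the median of all probe sets, probe sets without shared sequences and without chromosome 9 both counts stayed within 1.5 times. The log2 bound for MELTF was 3.42 with the higher floor and 3.48 with the offset. Over its 2 measured probe sets, a bound of 4.42 and a ratio of -0.23, the median was 2.09. The value reversed to -0.23 when probe sets with shared sequences were left out, because that removed the 1 probe set that was higher. The stress, hypoxia and G1/S lists lay outside the central 95% of random lists in all 14 settings run for lists, the stress list between -0.46 and -0.37; the hypoxia list went to 0.50 without shared-sequence probe sets and the G1/S list to 0.14 with the poly-A spikes. The others moved inside in some: the mitosis list in 3 settings, the adhesion list in 5, the TGF-beta list in 6 and the extracellular matrix list in 8. The mitosis value moved to 0.076 with the poly-A spikes, 0.080 for bright genes and 0.19 without shared-sequence probe sets, all 3 still outside. The TGF-beta value moved to 0.035 as the median of probe sets and reversed to -0.013 without shared-sequence probe sets, both inside, and the matrix value moved to 0.26 without them, outside. Chromosome 9 stayed between 0.46 and 0.47 in the alternatives run for chromosomes, and chromosome 8 moved to -0.026 under quantile normalization and -0.027 with the poly-A spikes. Of the 21 lists inside the central 95% as deposited, 4 lay outside under at least 1 alternative (iron metabolism in 1, plasminogen in 1, Ewing in 3, interferon in 4), and 12 turned direction under at least 1. With the shift of the all-gene median from its deposited value taken out, TTF1, ALDOC, SFRP2 and PLK3 were under 2-fold with the poly-A spikes. So were CDH5 and GADD45A with the hybridisation spikes, and KRT8 under quantile normalization and loess. Single named genes moved by more than the probe set spread in 24 pairs of gene and setting, stayed within it in 323, and reversed in 0. Unless stated, the cause was not tested. Signal over background limits the dim genes: the probe set spread was 0.40 below a mean signal of 500 and 0.21 above 2000.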

Other observations

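The families and single genes of the first paragraph, and the tests on chromosome 9 and on a loss of expression, were chosen after the values were seen. Clustered protocadherins, the neuronal adhesion proteins encoded in tandem arrays, had a relative median of 0.33 over 19 measured genes (percentile 99.92 of random lists), and between 0.11 and 0.35 over 6 scalings. Of these 19 genes, 13 lay above the median of all genes; PCDHB5 was 4.24-fold and PCDHGA4 2.47-fold higher in the clone. Others were lower, with log2 ratios of -0.82 for PCDHB4 and -0.49 for PCDHGB5 and PCDHGC3, and a bound of -0.74 for PCDHGA1; PCDHGA3 read 415.7 in the control and 191.3, under the floor, in the clone. Their sequences are similar, so probe sets can share transcripts. The 22 measured histone genes had a relative median of 0.078 (percentile 95.78), which ranged over the scalings from -0.026 with the hybridisation spikes (percentile 92.24) to 0.18 under quantile normalization (percentile 98.85) and 0.19 with the poly-A spikes (percentile 96.21). Members of this family went both ways: H2BC5 was 2.74-fold and H2AC6 2.62-fold higher, and H2AC25 was 3.32-fold lower. Genes with a ZNF symbol, without antisense, divergent and pseudogene symbols, had a relative median of 0.072 over 372 genes (percentile 99.95), above 0 under all 6 scalings. Of these, 218 lay above the median of all genes, while 5 were at least 2-fold higher and 7 at least 2-fold lower. The 5 measured genes of the MAGE, GAGE, PAGE and XAGE families of cancer-testis antigens had a relative median of -0.55, lower under all 6 scalings; MAGEA6, which has close paralogues, was 4.39-fold lower. MAOA, monoamine oxidase A, was 3.31-fold lower on the brightest of its 3 probe sets. MDFI, an inhibitor of myogenic factors, was 3.30-fold lower and OAT, ornithine aminotransferase, 3.12-fold lower, each on 1 probe set. FNBP1, which binds membranes and actin regulators, was 2.18-fold higher and lies on chromosome 9. Probe sets with several genes or none held 134 that were at least 2-fold higher and 104 at least 2-fold lower.

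The genes of chromosome 9 were higher in the clone along the whole chromosome. Among the 6 scalings, only quantile normalization and loess change genes relative to each other beyond the effects of the floor and of the probe set chosen. These did not account for the shift, since the lowest relative median over all 6 was 0.46. Nor did a few strong genes, since 89.4% of the genes lay above the median of all genes. Among runs of 40 neighbouring genes, from KANK1 to EHMT1, the lowest relative median was 0.28. The highest run on any other chromosome reached 0.25, on chromosome 13. A candidate explanation is a copy number difference, either more copies of chromosome 9 in clone 4 or fewer in the vector control, which would make part of the list of higher genes a property of the clones; no DNA measurement was used here. Whether the transfected melanotransferrin had a part in it stays open, because 1 clone per group was measured.

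The genes of the unfolded protein response and amino acid stress were lower relative to all genes under each of the 6 scalings. The relative median closest to 0 was -0.40. Of these scalings, only quantile normalization and loess change genes relative to each other beyond the effects of the floor and of the probe set chosen. Dim probe sets do not account for it, since the 24 members with a mean signal over 1000 had a relative median of -0.45, below the lower bound of -0.12 for random lists of bright genes. The culture state at harvest, such as density or age of the medium, may have differed between the clones and cannot be told apart from an effect of melanotransferrin, because there was 1 harvest per clone.

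More genes were lower than higher among those below the floor on 1 array, 115 against 33. The 191 probe sets for olfactory, taste receptor and hair keratin-associated genes, which should carry background alone, had a median log2 ratio of -0.55, and 130 of them were lower on the clone array. This is consistent with a lower background on the array of the clone. After quantile normalization the counts were 79 and 45, a ratio of 1.76, so a loss of expression of some of these genes is neither shown nor excluded.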
